A study of Gallus gallus with 48 samples.

How the data were processed

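Single-label hybridisations of chicken liver RNA were analysed from scanner output. The deposited scanner files hold the intensity of 64 spots per sample at both wavelengths, per the file headers, with a foreground mean, a local background median and its SD, and the percent of saturated pixels per spot. No normalization had been applied, per the file headers. The sample's own channel followed the dye in the labels. The spots form 32 adjacent pairs, for 20 genes, 10 beta-actin and Gapdh probes, a corn probe and a blank.

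The scanner files do not name the spots. Names came from a match to the table of processed log2 values deposited by the authors, whose columns name the probes. With the table's probe order and the Gapdh probes moved to the end, the scanner values of a sample correlated with that table at a median r of 0.978 across probes, at 0.9 or more in 41 of the 48 samples, and at 0.522 in the lowest, sample 4 of 10 weeks. Of the 31 probes with enough values, 29 were matched best by their own spots. All gene names rest on this match, which was found from the values. Of the 1536 values the authors deposited there, 480 are coded as missing. Its scaling per sample is not given in the sources used here. The deposited series table of background-subtracted intensity equals the scanner file in 45 columns, while those of samples 4, 5 and 6 of 6 weeks equal the scanner files of samples 5, 6 and 3. The scanner files were used here. The authors' log2 values of samples 4, 5 and 6 correlated with the scanner files of the same samples at 0.990, 0.858 and 0.910. In the series table the scanner file of sample 3 fills the columns of both sample 3 and sample 6, and that of sample 4 fills none. The series table therefore cannot be right for all 3 samples. Which file belongs to each of them within the 6-week group is otherwise not known. The dye would differ only for sample 5, labelled Cy3, whose column equals the file of sample 6, labelled Cy5. Column medians of that table ranged from 117 to 4277, and its values are on a linear scale, without centring.

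Intensities were corrected with normexp (offset 50), taken to log2, averaged over both spots of a probe, and centred on each sample's median over the 20 genes. Control spots entered normexp but no test of the panel. Fits used limma 3.58.1 in R 4.3.3, with age and dye as terms, moderated F tests, 6 pairwise contrasts, a slope per week, and the dye coefficient, with Benjamini-Hochberg adjustment and a threshold of 0.05. Pairwise contrasts were adjusted over genes and contrasts together. Gene lists were tested with fry where they held at least 3 genes. Brown-Forsythe and Kruskal-Wallis tests used permutations in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. A probe counted as above background when its foreground exceeded the background by 2 SD on average over its spots. A fold would be given only as a bound for a gene that was in no sample of an age above background, and every such bound was under 1, so none is given. Levels, fits and list tests still include these genes, as background-level values.

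The planned designs and alternatives and the gene lists were fixed before the data were examined. Further alternatives were added after seeing the data, and the averaging of the technical pair departs from the plan. The named-gene rule gave full statistics to the 5 genes with the smallest adjusted p of the F test when none passed, with ties ordered by unadjusted p. The plan named all 48 samples. The submitters' note lists samples 5 and 8 of 8 weeks as technical replicates of 1 labelled extract, although their labels name different dyes, so they were averaged to 47 units. Their profiles correlated at 0.673, and the highest value among the other 8-week pairs of opposite dye was 0.671, so the data do not single out this pair and the averaging rests on the note alone. For the blocked, spread and Kruskal-Wallis tests sample 5 alone stood for the pair. Slides were told apart by scan, giving 11 slides, of which 9 held more than 1 age. Background medians ranged from 1142.5 to 15950 per sample, and 4 spots in 2 samples were saturated. In sample 3 of 6 weeks the 2 spots of the fifth Gapdh probe had a local background over 5 times the sub-array's median. They distorted the normexp fit: the SD over its 20 genes was 0.10, against 2.13 with those spots left out and 2.61 with plain subtraction. The planned correction was kept, and fits with those spots left out, or without that sample, were added. Lists of cholesterol metabolism, triglyceride synthesis, transcription factors and blood cell markers had 0 members on the panel.

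The tests were run on simulated data of the same design, drawn as independent normal values with the residual SD of each gene. In 200 simulated panels per size the F test called 0.5% of unchanged genes set aside as targets, 44.9% of genes changed by 1 and 97.2% of genes changed by 2 on the log2 scale. The alternatives were other scalings, background corrections and filters, the authors' table, each dye alone, a replicate block, slide and position blocks, robust estimation and leaving out each sample. A median over the spots equals the mean with 2 spots. Fry needs complete values, so the lists were not run on the authors' table.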

Results

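Liver RNA of male Beijing-You chickens, an indigenous breed, was measured at 6, 8, 10 and 12 weeks of age on a small oligonucleotide panel of 20 genes, most of them genes of lipid metabolism and growth. Each age had 12 samples, of which 6 carried Cy3 and 6 carried Cy5, and each sample was hybridised alone to 1 sub-array of a slide. At 8 weeks samples 5 and 8 were technical replicates according to the submitters' note, so they were averaged and that age had 11 independent units. The other samples were listed as biological replicates. Signals were weak: a sample had a median of 5 of the 20 genes above background, and the range was 0 to 14. Pyruvate kinase (Pyr-kin) and UCP, the uncoupling protein, were above background in 35 of the 48 samples each, followed by OBR, the leptin receptor, in 26, and FAS, read here as fatty acid synthase, and H-FABP in 25 each. Some of these genes were also above background without the label. In the Cy3 channel of the 24 samples that carried only Cy5 this held for OBR in 17, Pyr-kin in 6, H-FABP in 4 and UCP and FAS in 0. In the Cy5 channel of the 24 samples that carried only Cy3 it held for Pyr-kin in 9, H-FABP in 8, OBR in 6, UCP in 2 and FAS in 0. In the Cy3-labelled samples OBR was above background in 16 of 24 and CPT-1 in 15, against 17 each without that label. In the Cy5-labelled samples OBR was in 10 of 24 and CPT-1 in 2, against 6 each without that label. Values of these genes over age may therefore not reflect sample RNA alone. Apo-B, Spot14b, AMPKg2, ACC, GH, IGF-2 and the mouse leptin probe OB(Mus) were above background in at most 5 samples. In sample 3 of 6 weeks, 2 control spots with extreme local background distorted the background correction, so that its 20 gene values had an SD of 0.10, against at least 0.98 in every other sample. It is included in the values below unless stated. The number of samples limits the precision of every value below. All are log2 intensities relative to the sample's median over the panel genes. With a median of 5 of the 20 genes above background, that reference is itself a background-level value in most samples. Values of the brighter genes may therefore partly follow how far a sample's signal rose over its background.

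The first comparison asked which panel genes differed between the 4 ages. None of the 20 genes passed the limma F test at an adjusted p of 0.05, and none had an unadjusted p under 0.05. The count was also 0 with the spots of extreme background left out of the correction. A Kruskal-Wallis permutation test also called 0 genes, with 1 gene at an unadjusted p under 0.05. The smallest p belonged to GHR, the growth hormone receptor, whose mean was -0.28 ± 0.94 (SD, n = 12) at 6 weeks, -0.58 ± 0.89 (SD, n = 11) at 8 weeks, -0.63 ± 0.74 (SD, n = 12) at 10 weeks and 0.29 ± 0.90 (SD, n = 12) at 12 weeks (limma p = 0.0555, adjusted p = 0.571). GHR was above background in 9 of the 48 samples, with 1 each at 6 and 8 weeks, 3 at 10 weeks and 4 at 12 weeks, so these means are mostly of background-level values. Spot14a, a thyroid hormone responsive protein of lipogenesis, had means of 0.37 ± 0.95, 0.50 ± 0.98, 0.41 ± 0.86 and 1.30 ± 1.02 (SD, n = 12, 11, 12 and 12) from the youngest to the oldest age (limma p = 0.0571, adjusted p = 0.571), and was above background in 21 samples. G-S-T, Spot14b and OBR followed, each with an adjusted p of 0.668 in limma. G-S-T was not well above background in any sample at 12 weeks, and Spot14b was above background in 4 of the 48 samples in all. Simulated panels with the spread of these data gave calls for 44.9% of genes changed by 1 on the log2 scale at 12 weeks. For genes changed by 2 it was 97.2%, so changes of about 2-fold in the measured value would often have been missed. The simulation drew samples as independent, while their correlation was 0.17 within slides and 0.25 within grid positions. It also moved the measured value itself, which a change in RNA may not do for genes near background.

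**Figure D1:**
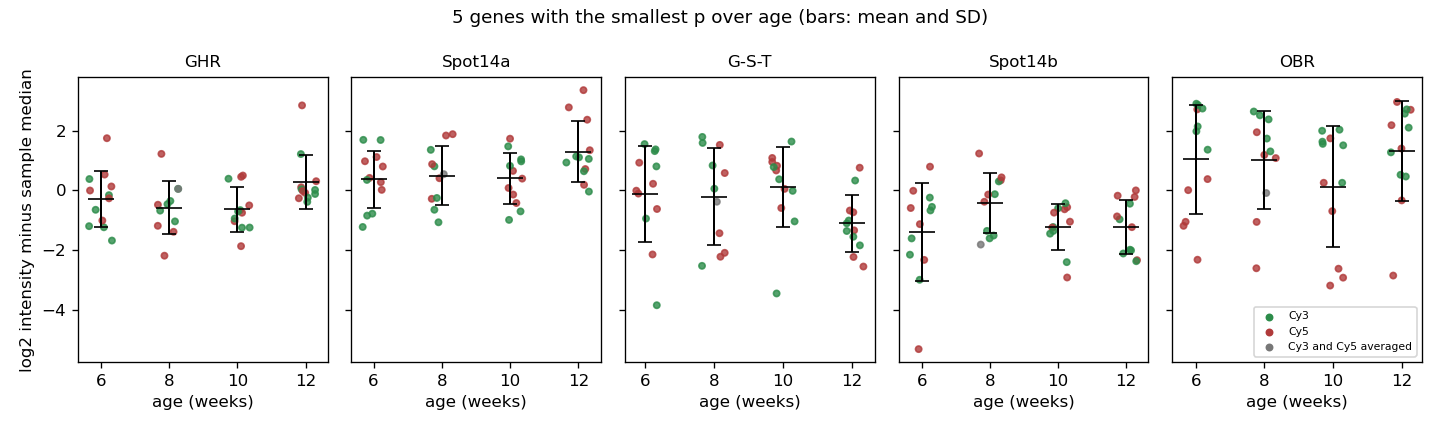
Log2 intensity minus the sample's median (vertical axis) against age in weeks for the 5 genes with the smallest p over age. Points are samples coloured by dye, and bars are the mean and SD. The ages overlap for all 5 genes, and Spot14a has its highest mean, 1.30, at 12 weeks.

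Pairs of ages were then compared gene by gene. None of the 120 differences passed an adjusted p of 0.05 in limma. An unadjusted p under 0.05 was found for 9, of which 7 were higher and 2 lower at the older age. The higher ones included Spot14a at 12 weeks against each younger age and GHR at 12 weeks against 10 and 8 weeks. These share the same 12-week samples, so the 7 are not separate results. GHR at 12 weeks exceeded its value at 10 weeks by 0.91 ± 0.36 (SE), with an adjusted p of 0.583 in limma. Spot14a at 12 weeks exceeded its value at 6 weeks by 0.92 ± 0.38 (SE), with the same adjusted p. OBR at 12 weeks exceeded its value at 10 weeks by 1.17 ± 0.57 (SE), and Spot14b at 8 weeks exceeded its value at 6 weeks by 0.98 ± 0.45 (SE), although it was above background in 2 samples and 1 sample there, again with an adjusted p of 0.583 in limma. In the Cy3 channel OBR was above background in 16 of 24 samples with the label and 17 of 24 without it. The lower ones, with that adjusted p too, were G-S-T at 12 against 10 weeks and AMPKg2 at 8 against 6 weeks, the latter at -0.74 ± 0.35 (SE). G-S-T was above background in 0 samples at 12 weeks and 4 at 10 weeks, so no size is given for it. AMPKg2 was above background in 1 sample at each age. The median standard error of a difference was 0.39. Sample profiles also followed the position of the sub-array on the slide. Classes of position were also used as a block. They pool sub-arrays by the offset between grid row and column, in a repeating pattern, and by odd or even column. A class can thus hold sub-arrays that lie apart, unlike an exact grid position. The classes were chosen after the values were seen, so fits with them cannot decide whether position explains a difference. With these classes as a block, the 12 minus 6 week value of Spot14a went from 0.92 to 0.18 and that of GHR from 0.57 to 0.22. With slide as a block they were 1.17 and 0.60. Of the differences at an unadjusted p under 0.05 in limma, 3 were higher and 7 lower at the older age with slide as a block, and 2 were higher and 8 lower with classes of position.

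A linear trend over the 4 ages was fitted to describe steady change with growth. None of the 20 slopes passed an adjusted p of 0.05 in limma, and 1 slope, that of Spot14a, had an unadjusted p under 0.05. It was 0.13 ± 0.06 (SE) per week (limma p = 0.0310, adjusted p = 0.574), and 0.12 ± 0.06 (SE) with p = 0.0603 in limma when the spots of extreme background were left out. UCP had a slope of 0.11 ± 0.08 (SE), with an adjusted p of 0.574 in limma, and one of 0.06 ± 0.08 (SE) when those spots were left out. Slopes were also taken within slides, without a term for dye, so on slides uneven in dye they mix age with dye. On slide 2 the 6-week samples carried Cy3 and the only 12-week sample Cy5. The highest within-slide slopes of Spot14a (0.71) and GHR (0.64) came from that slide. Within the 9 slides that held more than 1 age, the slope of Spot14a was above 0 on 6 slides and below 0 on 3, and that of GHR was above 0 on 7 and below 0 on 2. That of Spot14b was above 0 on 2 and below 0 on 7, that of G-S-T on 4 and 5, and that of OBR on 3 and 6, with Spot14b and G-S-T above background in 0 samples at 12 weeks. With slide as a block, limma called 0 genes by the F test, 0 pairwise differences and 0 slopes, while 2 genes (Spot14a and Spot14b, adjusted p = 0.320 each), 10 differences and 0 slopes had an unadjusted p under 0.05. With classes of position as a block, 3 genes had an unadjusted F-test p under 0.05 in limma. They were OBR (p = 0.00387), CPT-1 (p = 0.0189) and AMPKg2 (p = 0.0407), with adjusted p of 0.0774, 0.189 and 0.271.

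Gene lists of lipid metabolism were compared between 12 and 6 weeks. Of the 4 fatty acid synthesis genes, Spot14a had a 12 minus 6 week value of 0.92 and FAS one of 0.35. These were 0.81 and 0.03 when the spots of extreme background were left out, and 0.18 and 0.55 with classes of position as a block. ACC was not well above background in any sample of either age, nor was Spot14b at 12 weeks, so they have no direction here. In this list 0 genes passed the F test either over all genes or adjusted over the list alone. The list's test gave an adjusted p of 0.763 with fry and 0.528 with camera and an estimated correlation. Of the 6 hormone and receptor genes, GHR had a value of 0.57, IGF-1 one of -0.26 and OBR one of 0.26, which were 0.22, -0.04 and -0.15 with classes of position as a block. GH, IGF-2 and OB(Mus) were not well above background in any sample of either age. Here too 0 passed over all genes or adjusted over the list alone, with an adjusted p of 0.763 with fry and 0.920 with camera and an estimated correlation. Both list tests include the members that were not above background. The remaining lists held at most 2 panel genes and were not tested, and 0 of their genes passed over all genes or adjusted over the list alone. For fatty acid oxidation, UCP had a value of 0.69, or 0.31 with the spots of extreme background left out, and CPT-1 one of 0.05, or -0.37 with classes of position as a block. CPT-1, like OBR, was above background in the Cy3 channel about as often without the label (17 of 24) as with it (15 of 24). For fatty acid transport and as the only muscle marker, H-FABP had a value of -0.18, or 0.12 with classes of position as a block and -0.40 with the spots of extreme background left out. LPL, of lipoprotein transport and the only panel member of the lipolysis and adipocyte lists, had a value of -0.13, or -0.26 with the spots of extreme background left out. The hepatocyte markers were L-FABP, also of fatty acid transport, and Apo-B, also of lipoprotein transport. L-FABP was not well above background in any sample at 12 weeks, nor Apo-B at 6 weeks, so no difference is given for them. Over all 48 samples L-FABP was above background in 13 and Apo-B in 5, against 25 for the muscle marker H-FABP. How far the panel values follow liver RNA was not tested, which limits what the counts of 0 over age can show.

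The housekeeping genes were read from 5 probes each. Single beta-actin probes were above background in 2 to 20 of the 48 samples and single Gapdh probes in 8 to 29. Their means therefore include background-level values. Without the label, the probe Gapdh4 was above background in the Cy3 channel in 14 of 24 samples, Gapdh3 in 7 and Gapdh5 in 6. With Cy3 these probes were above background in 15, 16 and 6 of 24. The other Gapdh probes and all beta-actin probes were in 0 without that label. For the Cy5 channel, Gapdh4 was above background in 4 of 24 without the label and 12 with it. Means of Gapdh over age may therefore not reflect sample RNA alone. The mean over the beta-actin probes was 0.19 ± 0.67 at 6 weeks and 0.20 ± 1.15 at 12 weeks (SD, n = 12 each), and limma gave p = 0.812 over the 4 ages. Gapdh was at 0.77 ± 0.91 at 6 weeks and 0.32 ± 0.78 at 12 weeks (SD, n = 12 each), with limma p = 0.519 and an adjusted p of 0.812 for both genes. The 12 minus 6 week values of the beta-actin probes lay between -0.35 ± 0.70 (SE) and 0.66 ± 0.78 (SE), and those of the Gapdh probes between -0.74 ± 0.74 (SE) and -0.10 ± 0.65 (SE). Over the 4 ages the smallest unadjusted limma p of a single probe was 0.0733, for the second beta-actin probe.

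The spread between samples of an age was compared with a Brown-Forsythe permutation test, on values from which the mean of each dye had been removed. The SDs given here are of those values. None of the 20 genes passed an adjusted p of 0.05, and 3 had an unadjusted p under 0.05. FAS had SDs of 1.17, 1.59, 0.81 and 1.88 at 6, 8, 10 and 12 weeks (permutation p = 0.00708, adjusted p = 0.0971). OB(Mus) had SDs of 0.64, 1.07, 0.51 and 1.39 at those ages (permutation p = 0.00971, adjusted p = 0.0971), although it was above background in 1 sample. With the spots of extreme background left out, the adjusted p was 0.174 for FAS and 0.0604 for OB(Mus) in the permutation test. Apo-B followed, with an adjusted p of 0.323. In 10 simulated panels per size, with 40 changed genes in all, the test called 22.5% of genes whose SD at 12 weeks was 2 times that at the other ages, 70% at 3 times and 95% at 4 times. With no changed gene, those 10 panels gave 0.3 calls each on average, and 200 further panels gave 0.06.

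The dyes were compared because each age held both. CPT-1, which carries fatty acids into mitochondria, and OBR were lower with Cy5 than with Cy3, while FAS, UCP and AMPKg3 were higher, and these 5 of 20 genes passed an adjusted p of 0.05. The Cy5 minus Cy3 coefficient was -1.98 ± 0.32 (SE) for CPT-1, with an adjusted p of 1.6e-06 in limma, and 23 of the 24 Cy5 samples lay below the Cy3 median. For OBR it was -1.97 ± 0.41 (SE), with 20 of 24 Cy5 samples below the Cy3 median. For FAS it was 1.53 ± 0.40 (SE), for UCP 0.96 ± 0.35 (SE) and for AMPKg3 0.81 ± 0.29 (SE), with 19, 17 and 21 of 24 Cy5 samples above the Cy3 median. Slides were uneven in dye, and 1 slide held 10 of the 24 Cy5 samples. With slide as a fixed block, CPT-1 and OBR kept their calls at -1.74 and -2.77, while FAS at 0.99, UCP at 0.17 and AMPKg3 at 0.65 did not pass. AMPKg3 also did not pass on the authors' values, at 0.64 with an adjusted p of 0.634 in limma. Single samples also decided 2 of the calls. Without sample 7, 9 or 10 of 6 weeks or sample 1, 7 or 9 of 12 weeks neither UCP nor AMPKg3 passed in limma, which left 3 genes. UCP alone did not pass without sample 5 of 6 weeks, 10 of 8 weeks, 6 of 10 weeks or 12 of 12 weeks, nor AMPKg3 alone without sample 2 of 8 weeks. Over all samples left out in turn, the coefficient lay between 0.84 and 1.12 for UCP and between 0.70 and 0.91 for AMPKg3. OBR and CPT-1 also gave signal in the Cy3 channel of sub-arrays that carried only Cy5, in 17 of 24 samples each, and in the Cy5 channel of sub-arrays that carried only Cy3, in 6 of 24 each. Within the 8 slides that held both dyes, CPT-1 and OBR were lower with Cy5 on all 8, FAS was higher on 7, AMPKg3 on 6 and UCP on 3. These counts carry no term for age, so on slides where dye and age go together they mix both.

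**Figure D2:**
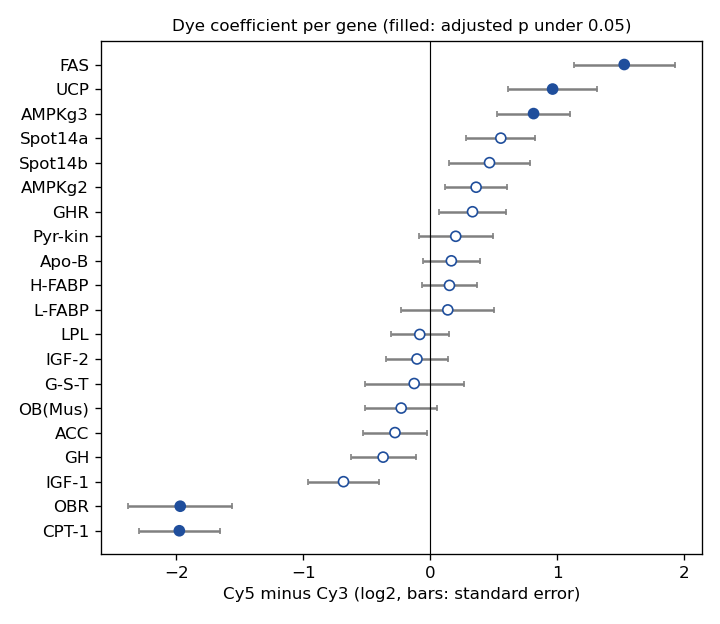
Cy5 minus Cy3 coefficient on the log2 scale (horizontal axis) for each of the 20 panel genes, with standard errors as bars. Filled points passed an adjusted p of 0.05. CPT-1 and OBR lie near -1.98 and -1.97, and FAS lies at 1.53.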

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

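The tests of the unlabelled-channel signal against the dye coefficient and of position on the slide were chosen after the results were seen, as was the use of splits within slides. On sub-arrays that carried only Cy5-labelled RNA, the Cy3 channel should hold no sample signal and enters no comparison. Even so, it was above background for OBR in 17 of 24 samples, for CPT-1 in 17 and for the fourth Gapdh probe in 14. The corn probe and the blank were above background there in 0 samples. Signal without the label was not confined to that channel: in the Cy5 channel of sub-arrays that carried only Cy3, Pyr-kin was above background in 9 of 24 samples, H-FABP in 8, and OBR and CPT-1 in 6 each.

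OBR and CPT-1 are the genes that passed the threshold as brighter with Cy3 than with Cy5. Across the 20 genes the mean Cy3-channel level on Cy5-labelled sub-arrays correlated with the Cy5 minus Cy3 coefficient at r = -0.86 (permutation p = 1e-05, the smallest the permutations can give; rho = -0.75), and at -0.66 without the 2 genes farthest from the median. Genes are not independent replicates. Leakage of Cy5 light into the Cy3 channel is argued against, since the channels correlated across probes within sub-arrays at a mean of 0.011 ± 0.044 (SE). A probe-bound signal in the Cy3 channel that does not come from the sample's label is a candidate explanation, and its origin was not tested. No biological explanation was tested, because dye is not a biological factor. In splits that ignore slide, 1 of 100, the real one, gave as many as 5 genes, and the highest of the others gave 4. Dye was uneven over slides, so this excludes chance only for samples taken as exchangeable between slides. With slide as a block and the dyes permuted within slides, the real count was 2, the highest of the others was also 2, and 2 of 100 splits, the real one included, gave as many. That share argues against chance, but 1 other split reached the real count, so chance is not excluded for it.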

How the results depend on the processing

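Position, slide as a fixed block, doubtful samples, the spots and sample of extreme background, the treatment of the technical pair and leaving out each sample for the dye count were alternatives chosen after seeing the data. The counts over age were 0 in every alternative run: 23 for the F test (smallest adjusted p = 0.0774, for OBR with the class of grid positions as a block), 23 for pairwise differences, 22 for slopes, 18 for gene lists and 4 for the spread. Leaving out each sample in turn also gave 0 for the F test, pairwise differences and slopes. With the replicate block, limma called 0 genes over age, 0 pairwise differences, 0 slopes, 0 lists and 5 genes for dye. Same-numbered samples of different ages did not deviate together (mean r = -0.01, from -0.58 to 0.66 over 72 pairs). With a median of 5 of the 20 genes above background per sample, this cannot exclude that the numbers pair the samples. The dye count of 5 was 15 without centring, 17 with quantile normalization within each dye, 11 with no background correction, 3 when only the 5 genes above background in at least 24 samples were tested, 3 with slide as a random block, 2 with slide as a fixed block, and 3 without the 4 doubtful samples. Centring subtracts 1 value per sample from every gene, so without it the coefficients of all 20 genes shift by the same amount by construction. FAS went from 1.53 to 2.33 and CPT-1 from -1.98 to -1.18. The shift shows that the sample medians were higher with Cy5, and the main coefficients are relative to those medians. Quantile normalization within each dye also keeps the level between dyes, with FAS at 2.30 and CPT-1 at -1.25. Fewer genes were tested under the filter. For the other settings the cause was not tested. It was 5 with the spots, or the sample, of extreme background left out, and from 3 to 6 with each sample left out in turn, where UCP did not pass in 10 of 48 fits and AMPKg3 in 7, while OBR, CPT-1 and FAS passed in all 48. OBR and CPT-1 kept their sign and call wherever they were tested, but not their size: CPT-1 was -1.98 in the main setting, -1.18 without centring, -0.44 with no background correction and -3.04 with a floor of 50, and OBR was -1.97, -1.17, -0.43 and -2.54. FAS, UCP and AMPKg3 were 2.33, 1.76 and 1.61 without centring and 0.77, 0.91 and 0.29 with no background correction. With slide as a random block UCP and AMPKg3 did not pass (adjusted p = 0.269 and 0.0631), nor did they without the 4 doubtful samples (0.0689 each), and AMPKg3 did not pass with classes of position as a block (0.0513). Of the 20 genes, 15 were above background in fewer than 24 samples, which limits what their comparisons can show. The other 5, tested alone, also gave 0 calls over age (smallest adjusted p = 0.754).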

Other observations

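The comparison of positions and the splits over age were made after the data were seen, and the tests of shared age and of probe order were set before their results were known. The probe profile of a sample resembled that of samples at the same place on other slides. Among 29 pairs at the same grid position the mean correlation across probes, with dye means removed, was 0.46, against -0.03 in other pairs, a difference of 0.496 (permutation p = 1e-05, the smallest the permutations can give). Sharing an age is argued against as the cause, since the 24 same-position pairs of different ages had a mean correlation of 0.472 ± 0.059 (SE). Pairs of 1 age had one of -0.01. The same-position pairs came from 11 positions and some share a sample, while that SE takes pairs as independent, so it is likely too small. A displaced probe order is argued against too, since 44 of 48 sub-arrays matched those at other positions best with no displacement. An effect of position on the slide, as from printing, is consistent with these values and remains a hypothesis, and what produces it was not tested.

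For the counts over age the real values were 0, so that 100 of 100 splits gave at least as many by construction and the comparison decides nothing about chance. The highest counts in the other splits were 2 for the F test, 3 for pairwise differences, 2 for slopes and 1 for lists.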
